A study of Mus musculus with 32 samples.

How the data were processed

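The deposited data describe polyadenylated RNA from GFP-high intestinal stem cells of mice, measured by high-throughput 3' digital gene expression, which counts reads near the 3' end of transcripts. Crypt cells were stained with an epithelial marker and a viability dye and sorted. The 32 libraries form 8 groups of 4: the genotypes WT, PparD (labelled Ppard-fl/fl), PparA (labelled Ppara-null) and PparDA (both), each on a control or a high-fat diet. The strain label is C57BL6 throughout. Whether and how the floxed Ppard alleles were recombined, and how long the diet lasted, are not given in the sources used here. The labels do not say that the 4 libraries of a group come from separate animals, so each p measures the spread between samples.

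The authors deposited a table of expected counts, estimates per gene and library that they had rounded to whole numbers, together with a table of log2(CPM + 1) values (CPM, counts per 1e+06). The submitters' processing notes name Salmon 1.1.0, edgeR 3.30.2, R 4.0.2 and the mouse build mm10, without the role of each. Use of molecular identifiers and the annotation release are not given. The deposited log2(CPM + 1) values, taken back to CPM, summed to 1e+06 in each library. Scaled to the counts, 89.7 to 91.3% of them were whole within a tolerance of 0.02, so these are estimates before rounding. They were used only as a check. Reads without molecular identifiers are not independent molecules, so floors given in counts cover counting error only.

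Column names gave each library's group and its number from 1 to 32, but no replicate number. The numbers fall into 4 runs of 8, each holding every group once. Gene identifiers were matched to GENCODE release M21 (GRCm38, the assembly called mm10) for symbols and coordinates. Of 54418 identifiers 54096 were matched, 322 were not, and 101 symbols were shared by more than 1 identifier.

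Genes were kept by the filterByExpr function of edgeR 4.0.16 over the 8 groups, with a minimum count of 10 and a minimum total of 15, which left 5872 genes holding 97.1 to 97.7% of the counts. Factors were computed by TMM (0.938 to 1.08). A quasi-likelihood model with 1 coefficient per group was fitted over all 32 libraries (glmQLFit and glmQLFTest, without a robust prior, in R 4.3.3). The common biological coefficient of variation was 21.7%. The 15 comparisons were the diet effect in each genotype, the difference of each mutant's diet effect from that in WT, each mutant against WT on each diet, and PparDA against PparD and PparA on the high-fat diet. Tests were two-sided and p was adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM factors and are the mean ± SD of a group.

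A set of 31 gene lists was fixed before the data were examined, as were the comparisons, tests and most other settings. Of these, 27 had at least 3 tested members and were tested with camera (limma 3.58.1), which compares a list with the other genes. The preset inter-gene correlation was 0.01, and p was adjusted over the 27 lists. The p with a correlation estimated for each list stands beside each call, and fry gives a test of each list on its own. The lists cover mitochondrial and peroxisomal fatty acid oxidation, ketone body metabolism, canonical PPAR targets, lipid uptake and lipoprotein assembly, cholesterol synthesis, fatty acid synthesis and LXR targets. They also cover intestinal stem cell markers, Wnt target and Notch ligand genes, proliferation, MHC class II, interferon response, antimicrobial and epithelial defence, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, glycolysis, NRF2 targets, the unfolded protein response, and proximal and distal small intestine. Markers of enterocytes, Paneth, goblet, enteroendocrine and tuft cells, lymphocytes, stromal and endothelial cells, red blood cells and the early response to dissociation complete the set.

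Named genes followed a rule. It takes the 10 largest rises and falls among called genes with a mean of at least 10 CPM and, for a comparison of 2 groups, no overlap of their ranges, leaving out unnamed and predicted genes. It adds genes fixed beforehand, among them Ppara, Ppard, Cpt1a, Pdk4, Angptl4, Plin2, Acaa2, Lgr5 and Olfm4, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, it takes the 5 with the smallest p. Where the rule gave more genes than the text holds, those named were chosen from them after their values were seen, mostly passing over pseudogenes. Some genes that the rule gave are not reported here, while gene counts and lists include them.

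The method was tested on simulated data with the spread of these libraries. With 4 libraries against 4, changes of 1.5-fold, 2-fold and 4-fold were called in 16.4, 58.2 and 86.4% of changed genes, and 8 of 5653 unchanged genes were called. For a difference between diet effects, 10.4, 22.4 and 75.8% were called, with 7 unchanged genes. Library totals ran from 612672 to 724155 counts (median 677216.5), so that 3 counts equal 4.14 to 4.9 CPM and 10 CPM equals 6.13 to 7.24 counts.

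Other settings fixed at that time were median-of-ratios factors, no filter on low counts, a filter of at least 20 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, a fit of only the libraries compared, an estimated correlation, and leaving out each library in turn. Settings chosen after seeing the data were the run of 8 as an added factor, runs 1 and 3 or runs 2 and 4 alone, library 5 left out, and other variance models of edgeR. The planned replicate factor was not fitted as such, since the columns carry none, but by sample title order the run of 8 matches it. Other splits of the libraries into groups of the same sizes were fitted over the libraries compared, and those of the 8 WT libraries also in the full model. Another 4 lists were too small to test.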

Results

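The series asked how a high-fat diet acts on intestinal stem cells through fatty acid oxidation, and whether Ppara and Ppard, nuclear receptors that fatty acids activate, are needed. RNA of sorted GFP-high stem cells was counted at the 3' end. WT control libraries are numbers 1, 9, 17 and 26, and WT high-fat libraries 2, 10, 18 and 25. PparD control libraries are 3, 11, 19 and 27, with high-fat 4, 12, 20 and 28. PparA control libraries are 5, 13, 21 and 29, with high-fat 6, 14, 22 and 30. PparDA control libraries are 7, 15, 23 and 31, with high-fat 8, 16, 24 and 32. Library totals spanned a ratio of 1.18, and 11683 to 12212 genes had at least 1 count.

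The library numbers form 4 runs of 8. In runs 1 and 3 the female-specific Xist stood at 465 to 928 CPM and the Y-linked Ddx3y at 0, and in runs 2 and 4 Ddx3y stood at 14.3 to 38.8 CPM and Xist at no more than 9.7 CPM. After group means were removed, all 32 libraries correlated best across genes with a library of their own run. Values for runs 1 and 3 and for runs 2 and 4 stand beside each comparison. They were fitted without a term for the run, so differences between single runs remain. With the run as a factor edgeR called more genes in each of the 15 comparisons, from 7 against 6 for the diet in WT to 146 against 16 for PparDA against PparA. Every group held the same place in each run except in WT, where control preceded high-fat in runs 1 to 3 and followed it in run 4, so that in the mutants place and diet go together.

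The targeted genes were too low to check the genotype labels. Ppara (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819, mm10) had 0 to 5 counts in each library. Its mean was 2.08 ± 1.74 CPM (SD, n = 4) in WT and 0.777 ± 0.897 CPM in PparA on the control diet, and 5.74 ± 1.99 and 2.78 ± 1.59 CPM on the high-fat diet. In PparDA it was 3.89 ± 2.78 CPM on the control and 1.98 ± 2.01 CPM on the high-fat diet. Ppard (ENSMUSG00000002250, chromosome 17, 28232700 to 28301474) had 0 to 7 counts, with 3.6 ± 1.9 CPM in WT and 3.89 ± 3.96 CPM in PparD on the control diet. Neither gene was tested, and 3' reads outside a deleted part would check nothing.

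In WT stem cells the high-fat diet raised genes for burning fatty acids. Fabp1, which carries fatty acids inside epithelial cells, rose by the most on the log2 scale. Acaa2, Acadvl, Eci2 and Ech1, enzymes of mitochondrial β-oxidation, rose as well. No gene fell past the threshold, and the stem cell genes Lgr5, the receptor by which these cells are defined, and Olfm4 did not pass it either.

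Fabp1 (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023) stood at 1410 ± 659 CPM (SD, n = 4) on the high-fat and 139 ± 28.7 CPM on the control diet, a log2 fold change of 3.33 ± 0.64 (SE; edgeR adjusted p = 0.035). The log2 fold changes of Eci2, Acadvl, Acaa2 and Ech1 were 1.09 ± 0.23, 0.91 ± 0.19, 0.80 ± 0.16 and 0.67 ± 0.12 (adjusted p = 0.04, 0.036, 0.035 and 0.015). Cpt1a, which admits fatty acids to mitochondria, was at 35.9 ± 5.91 and 16.8 ± 11.4 CPM, and Angptl4, a lipase inhibitor induced by PPARs, at 7.2 ± 3.09 and 1.85 ± 2.2 CPM, without passing (adjusted p = 0.53 and 0.58). Lgr5 changed by −0.07 ± 0.25, Olfm4 by 0.18 ± 0.13 and Plin2, a lipid droplet coat protein, by −0.23 ± 0.17 (adjusted p = 0.98, 0.82 and 0.82). Pdk4 was too low to be tested in any comparison.

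In all, 6 of 5872 genes were called in WT, all higher, and 450 had an unadjusted p under 0.05 where 294 would by chance. The count fell to 2 without library 1, 9 or 18 and to 0 without library 10, 17 or 25. The calls were lost without any 1 of several libraries: Fabp1 without 1, 9, 10, 17, 25 or 26 (adjusted p = 0.057 to 0.22) and Eci2 without 1, 9, 10, 17, 18, 25 or 26 (0.056 to 0.26). Acadvl was lost without 9, 10, 17, 18, 25 or 26 (0.075 to 0.22), Acaa2 without 1, 10, 17, 18, 25 or 26 (0.057 to 0.22) and Ech1 without 10, 17 or 25 (0.062 to 0.12). With a robust variance prior Fabp1 had an adjusted p of 0.1 (2e-99 to 0.24 over the alternatives). Within runs 1 and 3 the fit called 5 genes and within runs 2 and 4 it called 4, of which 0 and 4 were among the 6.

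The mitochondrial fatty acid oxidation list moved upward as a whole in WT (camera adjusted p = 9.3e-15). Of its 19 tested genes 16 were higher, 4 were called over all genes and 10 when adjusted over the list alone, with a median log2 fold change of 0.59. It also passed with an estimated correlation (adjusted p = 0.012), within runs 1 and 3 (0.0041) and within runs 2 and 4 (2.2e-17; 2.2e-17 to 0.012 over the alternatives). Canonical PPAR targets rose too (median 0.58, 3 of 17 called and 4 when adjusted over the list alone; adjusted p = 1.9e-06, and adjusted p = 0.09 with an estimated correlation). The plot of CPM in each library shows 5 of these genes.

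**Figure D1:**
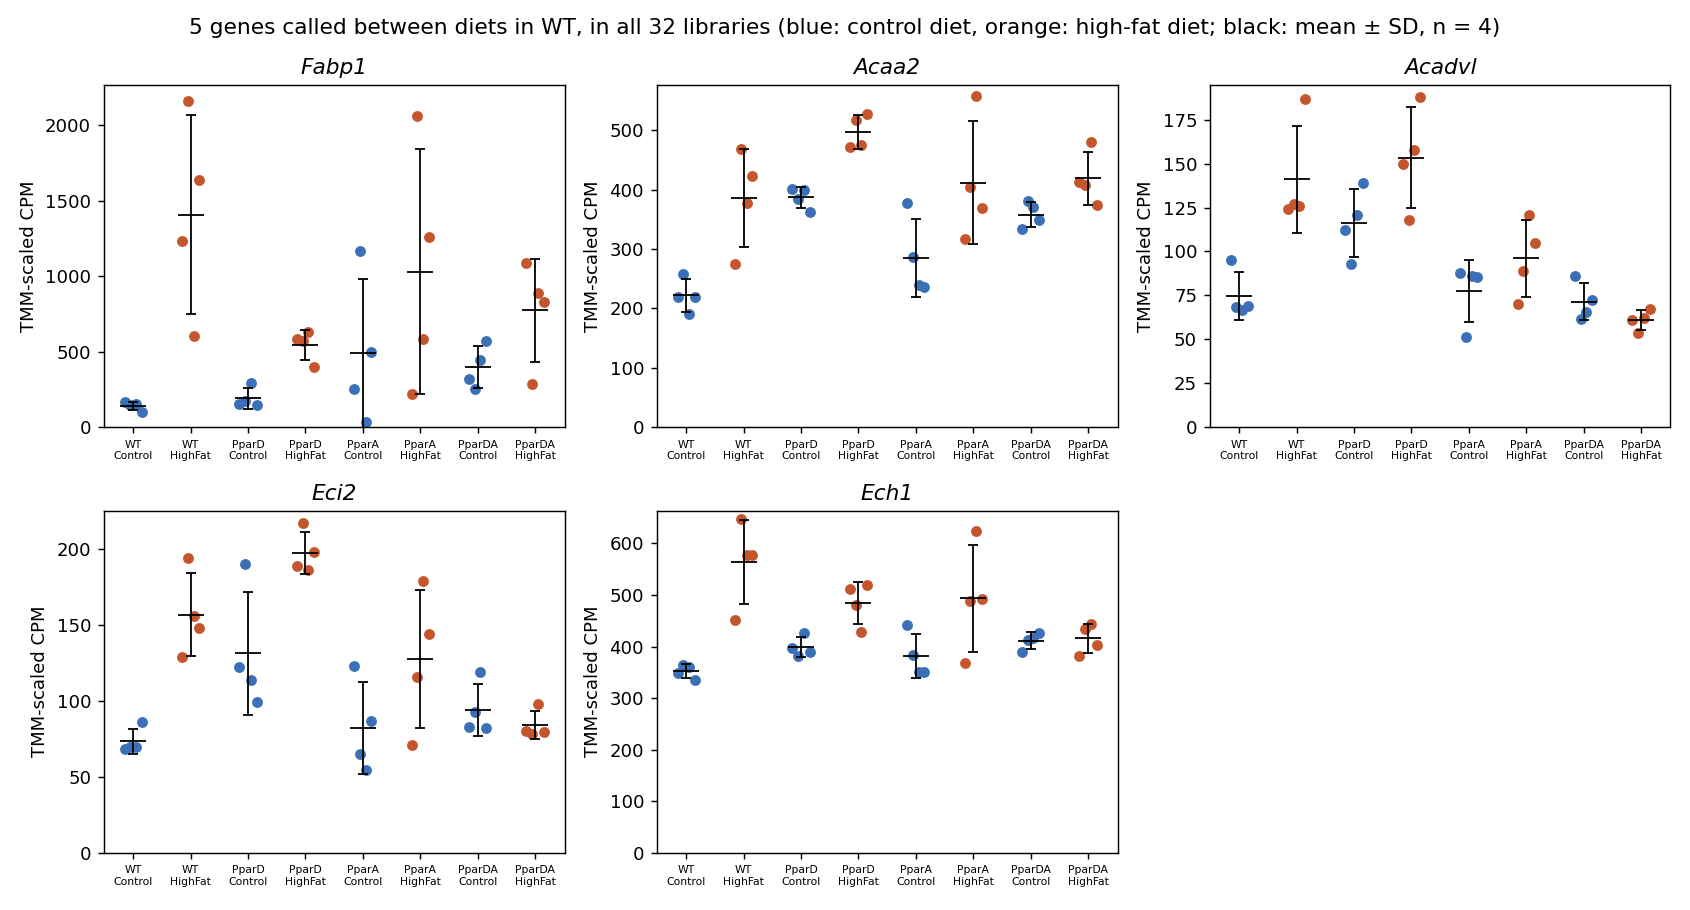
CPM of Fabp1, Acaa2, Acadvl, Eci2 and Ech1 in each library (points) of the 8 groups, with mean and SD (bars). In WT all 5 were higher on the high-fat diet, and PparD control libraries had an Acaa2 mean of 387 CPM against 222 CPM in WT control libraries.

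Markers of secretory cells moved with the diet in WT. Of 15 markers of Paneth cells, niche cells beside the stem cells, 14 were higher (median 1.51; adjusted p = 4.5e-07, and adjusted p = 0.37 with an estimated correlation), among them the defensin Defa22 (752 ± 849 and 150 ± 105 CPM) and Ang4 (313 ± 299 and 81.8 ± 105 CPM). Their sum was 21500 ± 16400 CPM on the high-fat diet, or 13700 CPM without library 2 (44900 CPM), and 7430 ± 5750 CPM on the control diet, or 4560 CPM without library 26 (16000 CPM). All 12 goblet cell markers were higher (median 0.64, 1 when adjusted over the list alone; adjusted p = 6.4e-07, and 0.16 with an estimated correlation), with the mucus gene Zg16 at 116 ± 50.8 and 37.6 ± 17.1 CPM. All 7 enteroendocrine markers were higher (median 0.78; adjusted p = 0.011, and 0.52 with an estimated correlation), with Sct, encoding secretin, at 26.1 ± 13 and 11.7 ± 6.16 CPM. That list lost its call without library 10, 18 or 26 (0.061 to 0.45). MHC class II genes, which present antigen, fell (median −0.74; adjusted p = 0.022, and 0.62 with an estimated correlation), with Cd74 at 182 ± 143 and 341 ± 145 CPM and H2-Ab1 at 56.5 ± 45.9 and 100 ± 33.2 CPM. This call was lost without any 1 of libraries 2, 10, 17 or 25 (0.12 to 0.19). The stem cell marker list fell slightly (median −0.30, 0 of 20 called and 1 when adjusted over the list alone; adjusted p = 0.00016, and 0.13 with an estimated correlation).

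In PparD stem cells Rps24, which encodes a protein of the small ribosomal subunit, Ppt2, a lysosomal thioesterase, Ptms, a small acidic nuclear protein, and Stk11, a kinase that senses energy, were lower on the high-fat diet. The fatty acid oxidation list rose as a set although none of its genes was called, with an adjusted p of 0.14 with an estimated correlation. Goblet and enteroendocrine markers were higher and antimicrobial genes lower as sets, calls lost with an estimated correlation (adjusted p = 0.14, 0.25 and 0.17).

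Rps24 (ENSMUSG00000025290, chromosome 14, 24487125 to 24496959) stood at 1740 ± 168 CPM (SD, n = 4) on the high-fat and 7160 ± 732 CPM on the control diet, a log2 fold change of −2.04 ± 0.17 (adjusted p = 2.8e-09). Ppt2, Ptms and Stk11 changed by −2.35 ± 0.28, −2.67 ± 0.44 and −2.02 ± 0.37 (adjusted p = 3.6e-06, 0.0021 and 0.0094). In all 5 genes were called, and 293 had an unadjusted p under 0.05, near the 294 of chance. Stk11 lost its call without library 12, 27 or 28 (0.053 to 0.08). Rps24 also differed between WT libraries by their place in the run, by 0.79 ± 0.12 (adjusted p = 0.00048). Both pairs of runs called 2 genes, all among the 5. Acaa2 was at 497 ± 28.9 and 387 ± 17.2 CPM, Angptl4 at 27.7 ± 5.76 and 11.5 ± 3.96 CPM, and Fabp1 at 545 ± 101 and 191 ± 70.1 CPM, with adjusted p of 0.93, 0.79 and 0.91.

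In PparD 15 of 19 fatty acid oxidation genes were higher on the high-fat diet (median 0.36; adjusted p = 8.8e-07, and adjusted p = 0.14 with an estimated correlation). Its adjusted p was 0.0017 within runs 1 and 3 and 3.9e-05 within runs 2 and 4 (1.4e-07 to 0.14 over the alternatives), and the smallest single-gene p was that of Acadl, an acyl-CoA dehydrogenase (0.92 ± 0.33). The calls that follow were each lost with an estimated correlation. PPAR targets rose (median 0.09; adjusted p = 0.021, estimated 0.42) but not without 3, 4, 11, 12 or 27 (0.059 to 0.14). Lipid uptake genes rose (0.21; 0.009, estimated 0.43). Cholesterol synthesis genes fell (median −0.26; 0.013, estimated 0.42), not so without library 11 (0.41) or 20 (0.07). Fatty acid synthesis genes fell (−0.26; 0.026, estimated 0.14), not so without 3, 4, 11, 19 or 20 (0.063 to 0.087). Stem cell markers fell (−0.14; 0.016, estimated 0.42), not so without library 20 (0.07) or 27 (0.35), and MHC class II genes fell (−0.84; 0.0073, estimated 0.42), not so without library 4 (0.05), 11 (0.12) or 20 (0.24).

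Antimicrobial genes fell in PparD on the high-fat diet (median −1.68 over 5 genes, 4 when adjusted over the list alone, 1 of them higher; adjusted p = 0.009, and 0.17 with an estimated correlation). Reg3b, a lectin that kills bacteria, was at 131 ± 127 and 1450 ± 1670 CPM and Reg3g at 153 ± 128 and 967 ± 1230 CPM, and the call was lost without library 11 (0.063) or 20 (0.07). Goblet markers rose (median 0.77; adjusted p = 2.6e-09, estimated 0.14), with Muc2, the main mucin, at 18.3 ± 6.47 and 4.98 ± 4.28 CPM and Tff3 at 884 ± 203 and 505 ± 135 CPM. Enteroendocrine markers rose (median 1.33; 0.00035, estimated 0.25). Paneth markers rose (0.30; 0.0068, estimated 0.55), not so without 3, 12, 19 or 28 (0.061 to 0.15). Oxidative phosphorylation genes rose slightly (0.10, 24 of 27 higher; 0.009, estimated 0.42), not so without library 27 (0.28).

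In PparA stem cells the ribosomal protein genes Rpl28 and Rps4x were higher on the high-fat diet, together with Trmt112, a cofactor of methyltransferases, Hint1, a nucleotide hydrolase, and Tbca, which helps to fold tubulin. Anp32a, a histone-binding phosphatase inhibitor, was lower. Fatty acid oxidation genes rose as a set, as did goblet, Paneth and tuft cell markers, while proliferation genes fell slightly. With an estimated correlation these calls were lost (adjusted p = 0.17, 0.22, 0.55, 0.52 and 0.52).

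Rps4x (ENSMUSG00000031320, chromosome X, 102184941 to 102189394) stood at 26600 ± 3770 CPM (SD, n = 4) on the high-fat and 7230 ± 590 CPM on the control diet, a log2 fold change of 1.88 ± 0.16 (adjusted p = 9.9e-09). Rpl28, Trmt112, Hint1, Tbca and Anp32a changed by 2.39 ± 0.21, 1.62 ± 0.18, 0.83 ± 0.11, 0.71 ± 0.15 and −0.85 ± 0.18 (adjusted p = 1e-08, 8.6e-07, 3.5e-05, 0.032 and 0.046). Rps4x also differed between WT libraries by place, by 0.75 ± 0.10 (adjusted p = 7.7e-05). The count was 8, with 7 higher, and 340 genes had an unadjusted p under 0.05. It was 14 without library 6 and 5 without 13, 21 or 30. Tbca was lost without any 1 of 13, 14, 21, 22, 29 or 30 (0.058 to 0.21) and Anp32a without any 1 of 5, 13, 14, 21, 22 or 30 (0.11 to 0.24). Runs 1 and 3 called 4 genes, all among the 8, and runs 2 and 4 called 8, of which 4 were among them.

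In PparA the β-oxidation gene Hadha gained a call without library 5, a control (adjusted p = 0.003), as did Acadl (0.039, and 0.0086 without library 6). Acadl changed by 1.81 ± 0.41 (adjusted p = 0.066) and Acaa2 by 0.53 ± 0.16 (0.35). In PparA 14 of 19 fatty acid oxidation genes were higher (median 0.33, 9 when adjusted over the list alone; adjusted p = 4.5e-08, and 0.17 with an estimated correlation). Its adjusted p was 0.015 within runs 1 and 3 and 1.2e-06 within runs 2 and 4 (2.1e-12 to 0.17 over the alternatives). PPAR targets rose (median 0.26, 2 when adjusted over the list alone; 0.00014, and 0.22 with an estimated correlation).

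The other list calls in PparA were also lost with an estimated correlation. Goblet markers rose in 12 of 12 genes (median 0.53; adjusted p = 1.8e-05, estimated 0.22), with Fcgbp, a mucus protein, at 152 ± 117 and 58.5 ± 31.9 CPM and Muc2 at 40.4 ± 20.7 and 16.6 ± 9.3 CPM. Paneth markers rose (1.04; 0.014, estimated 0.55), not so without 14, 21 or 30 (0.17 to 0.24). Tuft cell markers rose (0.59; 0.033, estimated 0.52), not so without 14, 21 or 22 (0.12 to 0.39). Lipid uptake genes rose (0.28; 0.03, estimated 0.52), not so without 5, 14, 21 or 30 (0.23 to 0.88). Genes of the proximal small intestine rose (0.54, 2 when adjusted over the list alone; 0.017, estimated 0.22), not so without library 14 (0.36) or 21 (0.16). Proliferation genes fell (−0.14; 0.033, estimated 0.52), not so without 14, 21, 22, 29 or 30 (0.078 to 0.37). Oxidative phosphorylation genes fell (−0.06; 0.033, estimated 0.52), not so without 13, 14, 22, 29 or 30 (0.072 to 0.19).

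In PparDA stem cells Ppt2 and Cops2, a subunit of the COP9 signalosome, were lower on the high-fat diet, and the fatty acid oxidation list did not pass its test. Cholesterol synthesis and glycolysis genes rose as sets, and tuft cell markers fell, but not with an estimated correlation (adjusted p = 0.51, 0.63 and 0.63).

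Ppt2 was at 8.59 ± 4.82 CPM (SD, n = 4) on the high-fat and 36.9 ± 4.9 CPM on the control diet in PparDA, a log2 fold change of −2.08 ± 0.30 (adjusted p = 6e-04). Cops2 changed by −0.65 ± 0.13 (adjusted p = 0.041), a call lost without any 1 of libraries 7, 8, 16, 23, 24, 31 or 32 (0.052 to 0.25), which left a count of 1. These 2 were the genes called, with 516 at an unadjusted p under 0.05; DESeq2 called 35 genes, of which 0 were among the 2. The next smallest p were those of Wnk1, a kinase, Rps15 and Ncl, encoding nucleolin, which missed the threshold (adjusted p = 0.19, 0.24 and 0.24). Acaa2 was at 419 ± 45.2 and 358 ± 21.3 CPM (adjusted p = 0.74). Both pairs of runs called 0 genes.

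In the fatty acid oxidation list 8 of 19 genes were higher in PparDA on the high-fat diet (median −0.02; adjusted p = 0.9, and 1 with an estimated correlation). Within runs 1 and 3 the adjusted p was 0.93, with the direction turned, and within runs 2 and 4 it was 0.61 (0.61 to 1 over the alternatives). All 15 cholesterol synthesis genes were higher (median 0.46; adjusted p = 8.1e-05, and 0.51 with an estimated correlation), with the regulator Srebf2 at 21.1 ± 4.4 and 12.2 ± 1.74 CPM. Tuft cell markers fell (median −0.62, 1 when adjusted over the list alone; 0.03, and 0.63 with an estimated correlation), with Rgs13 at 54.6 ± 9.21 and 112 ± 56.3 CPM, but not without any 1 of 8, 15, 23, 24 or 31 (0.054 to 0.27). Glycolysis genes such as Pkm (290 ± 69.3 and 220 ± 29.3 CPM) rose (median 0.19, 9 of 11 higher; 0.03, and 0.63 with an estimated correlation), but not without any 1 of 7, 8, 23, 24 or 32 (0.051 to 0.082).

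The diet calls of different genotypes rest on different libraries. The single gene called in the same direction in more than 1 genotype was Ppt2, lower in PparD and PparDA, where 0.0017 genes would be by chance (Fisher's exact test, two-sided p = 0.0017). The plot shows the fold changes of the fatty acid oxidation list.

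**Figure D2:**
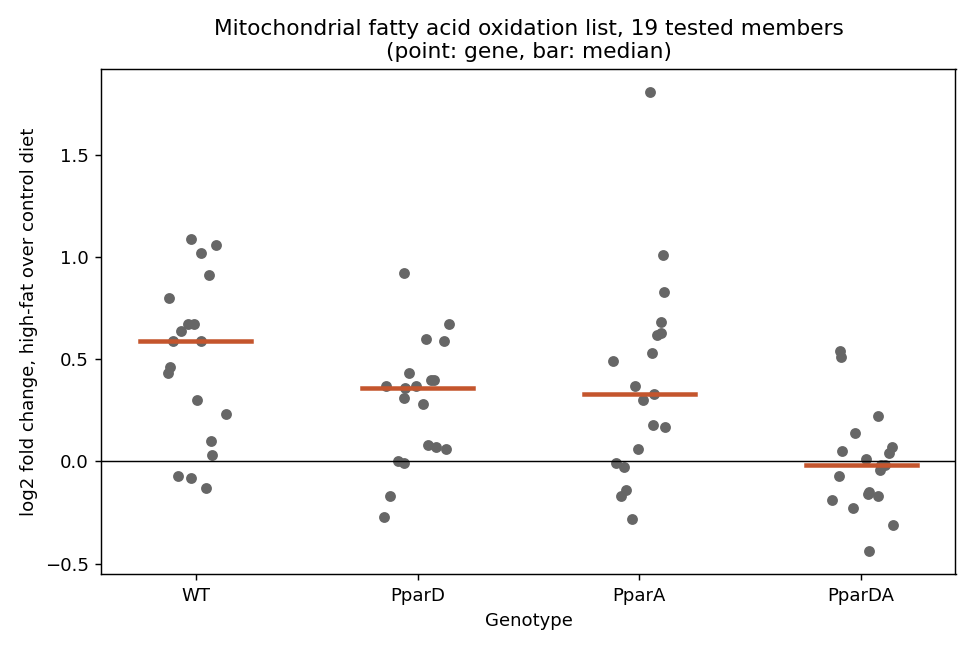
Log2 fold change, high-fat over control diet, of the 19 tested mitochondrial fatty acid oxidation genes (points) in each genotype, with the median (bar). The medians were 0.59 in WT, 0.36 in PparD, 0.33 in PparA and −0.02 in PparDA.

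The diet effect of each mutant was also tested against that of WT. In PparDA the fatty acid oxidation list was above WT on the control diet and did not rise on high fat. The lower diet effect was lost with an estimated correlation (adjusted p = 0.087), and edgeR called no gene. In PparD, Rps24 and Clta, a clathrin light chain of endocytic vesicles, responded more negatively. In PparA, Rpl28, Rps4x, Trmt112, Hint1, Deptor, an mTOR inhibitor, and Golga1, a Golgi protein, responded more positively. Anp32a and Rab25, a recycling GTPase, responded more negatively there.

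For PparDA against WT 0 genes were called by edgeR, 1 by DESeq2 and 4 by edgeR with the run as a factor, with 339 at an unadjusted p under 0.05. All 19 fatty acid oxidation genes had a lower diet effect in PparDA (median −0.48, 4 when adjusted over the list alone; adjusted p = 1.2e-09). The adjusted p was 0.087 with an estimated correlation and 0.041 by fry. Within runs 1 and 3 it was 0.059 and within runs 2 and 4 3.1e-11 (3.1e-11 to 0.087 over the alternatives). The list's summed CPM was 2370 ± 148 in WT and 2920 ± 66.8 in PparDA on the control diet. On the high-fat diet it was 3230 ± 286 and 2910 ± 197. Acadvl differed by −1.14 ± 0.27, Ech1 by −0.66 ± 0.16, Eci2 by −1.26 ± 0.32 and Fabp1 by −2.37 ± 0.85 (adjusted p = 0.43, 0.43, 0.44 and 0.64). Rps24 (−1.12 ± 0.23; adjusted p = 0.22) gained a call without library 25 (0.012) or 26 (0.006), and the count became 1 and 2. Runs 1 and 3 called 2 genes and runs 2 and 4 called 1.

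Canonical PPAR targets (median −0.52, 1 when adjusted over the list alone; adjusted p = 0.00024, and 0.22 with an estimated correlation) had a lower diet effect in PparDA. All 12 goblet markers, Klk1 among them (−0.95 ± 0.28), did too (median −0.61, 1 when adjusted over the list alone; 5.4e-05, and 0.34 with an estimated correlation). So did all 15 Paneth markers, with Lyz1, encoding lysozyme, at −2.16 ± 1.11 (median −1.71; 2e-04, and 0.53 with an estimated correlation), but not without library 31 (0.13).

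For PparD against WT 3 genes were called, among them Rps24 (−2.55 ± 0.23, adjusted p = 3.6e-08) and Clta (−2.75 ± 0.54, 0.037), with 212 at an unadjusted p under 0.05. Clta (ENSMUSG00000028478, chromosome 4, 44004452 to 44032846) lost its call without any 1 of libraries 1, 2, 3, 4, 9, 10, 11, 12, 17, 18, 20, 27 or 28 (0.06 to 0.14). It differed between WT libraries by place by 2.17 ± 0.18 (adjusted p = 2e-09). The count was 6 without library 25 or 26, 6 within runs 1 and 3, of which 3 were among the 3, and 1 within runs 2 and 4, which was not. Of the fatty acid oxidation genes 16 of 19 were lower (median −0.20; adjusted p = 0.034, and 0.9 with an estimated correlation). Its adjusted p was 0.72 within runs 1 and 3 and 0.00073 within runs 2 and 4 (0.00073 to 0.9 over the alternatives). The call was lost without any 1 of 9, 10, 11, 12, 17, 18, 19, 20, 25 or 26 (0.058 to 0.2).

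PPAR targets also had a lower diet effect in PparD than in WT (median −0.39; adjusted p = 0.038, and 0.9 with an estimated correlation), but not without any 1 of 9, 10, 11, 17, 18, 19, 20, 25, 26 or 28 (0.064 to 0.2). Cholesterol synthesis genes (−0.35; 0.0068, and 0.88 with an estimated correlation) lost their call without library 11 (0.071) or 26 (0.11). Antimicrobial genes (−2.50; 0.02, and 0.49 with an estimated correlation) lost it without 10, 11, 20 or 26 (0.071 to 0.093).

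For PparA against WT 9 genes were called and 481 had an unadjusted p under 0.05. The differences were 2.28 ± 0.29 for Rpl28, 1.51 ± 0.23 for Rps4x, 1.49 ± 0.26 for Trmt112 and 0.79 ± 0.16 for Hint1 (adjusted p = 6.3e-05, 0.00059, 0.0051 and 0.024). They were 1.57 ± 0.34 for Deptor, 1.77 ± 0.37 for Golga1, −1.25 ± 0.25 for Anp32a and −1.03 ± 0.20 for Rab25 (0.042, 0.038, 0.024 and 0.015). The count was 4 without library 10, 21 or 22, 5 without 1, 25 or 30, and 16 without 26. Calls were lost for Hint1 without 1, 10, 13, 18, 21, 22, 25 or 30 (0.055 to 0.09) and Rab25 without 10 (0.055). Deptor lost its call without 1, 2, 10, 14, 17, 18, 21, 22, 25, 29 or 30 (0.055 to 0.2), Golga1 without 1, 2, 9, 10, 14, 17, 21, 22, 25, 29 or 30 (0.056 to 0.17) and Anp32a without 1, 2, 10, 14, 17, 21, 22 or 30 (0.051 to 0.094). Runs 1 and 3 called 3 genes and runs 2 and 4 called 1, each with 1 among the 9. No list passed: the fatty acid oxidation list had a median of −0.10 (adjusted p = 0.44, and 0.89 with an estimated correlation), 0.84 within runs 1 and 3 and 0.3 within runs 2 and 4 (0.3 to 0.95 over the alternatives).

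**Figure D3:**
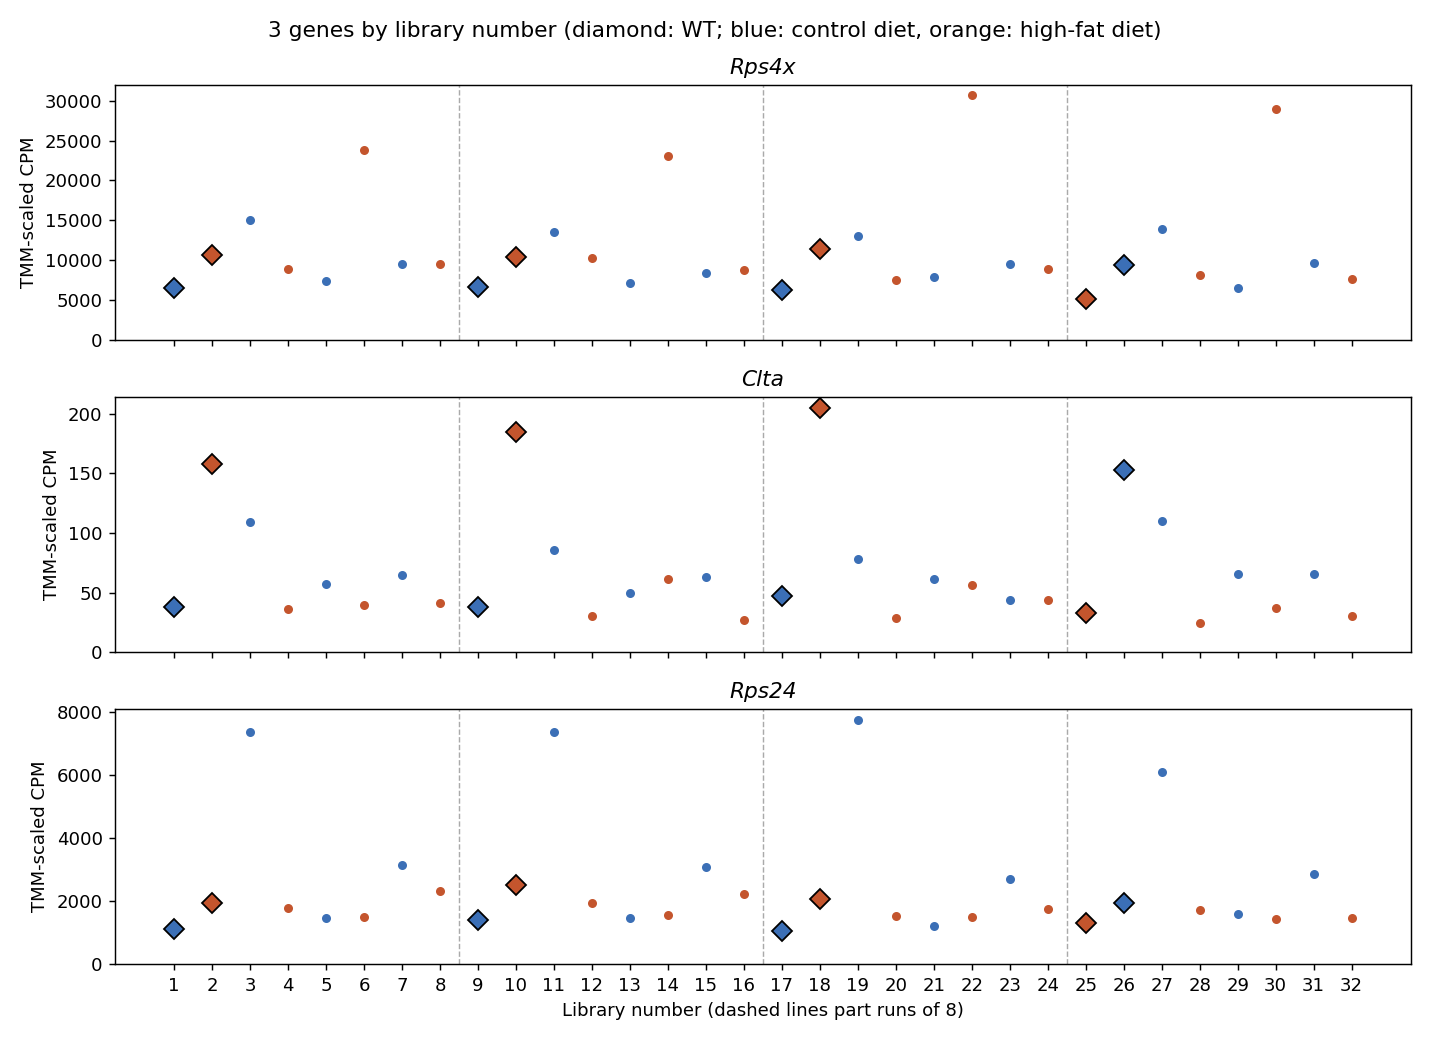
CPM of Rps4x, Clta and Rps24 by library number, with WT libraries as diamonds and dashed lines parting the runs of 8. In WT, Clta differed by 2.17 and Rps24 by 0.79 on the log2 scale between the places in the run.

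On the control diet PparD stem cells already had higher fatty acid oxidation genes than WT. Acaa2, a PPAR target, was higher, and the whole list was higher. Rps24, Ppt2 and Ptms, which were lower on the high-fat diet in PparD, were higher as well. Magohb, a splicing factor, and Ccnd2, a cyclin that drives entry into the cell cycle, were lower.

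Acaa2 (ENSMUSG00000036880, chromosome 18, 74779197 to 74806208) was at 387 ± 17.2 CPM (SD, n = 4) in PparD and 222 ± 27.6 CPM in WT on the control diet, a log2 fold change of 0.80 ± 0.16 (adjusted p = 0.012), a call lost without library 17 (0.086) or 19 (0.051). Rps24 changed by 2.38 ± 0.17, Ppt2 by 2.70 ± 0.29 and Ptms by 2.06 ± 0.41 (adjusted p = 7.9e-11, 6.4e-07 and 0.016). Magohb changed by −1.18 ± 0.22 and Ccnd2 by −0.92 ± 0.19 (0.0087 and 0.019). Ptms was lost without 1, 17, 19 or 27 (0.065 to 0.11), Magohb without 3 (0.052) and Ccnd2 without 9, 11, 17 or 19 (0.07 to 0.14). Angptl4 was at 11.5 ± 3.96 and 1.85 ± 2.2 CPM and Eci2 at 131 ± 40.4 and 73.4 ± 8.4 CPM, not called (0.26 and 0.21). In all 12 genes were called, 10 higher, with 453 at an unadjusted p under 0.05. The count was 7 without library 17 or 19, 13 within runs 1 and 3 and 3 within runs 2 and 4, of which 5 and 3 were among the 12.

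In PparD 17 of 19 fatty acid oxidation genes were higher than in WT on the control diet (median 0.42, 1 called and 10 when adjusted over the list alone; adjusted p = 2.1e-11). It also passed with an estimated correlation (0.042), within runs 1 and 3 (0.00049) and within runs 2 and 4 (4.6e-10; 1.9e-12 to 0.042 over the alternatives). PPAR targets rose alike (median 0.42, 2 called and 4 when adjusted over the list alone; 3.4e-07, and 0.048 with an estimated correlation). Of all list results in the 15 comparisons, these 2 and the fatty acid oxidation list in WT were the ones that passed with an estimated correlation. Goblet markers were lower (median −0.70; 0.00012, and 0.56 with an estimated correlation), with Muc2 at 4.98 ± 4.28 and 18.4 ± 8.66 CPM. Enteroendocrine markers were lower (−1.19; 0.0025, and 0.56 with an estimated correlation), with Sst, encoding somatostatin, at 0.739 ± 1.48 and 7.54 ± 6.69 CPM, but not without library 11 (0.08).

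On the control diet PparA stem cells differed from WT in Cyb5r3, a reductase of the endoplasmic reticulum and mitochondria, Cmbl, a hydrolase, and Hsd17b13, a lipid droplet enzyme, which were higher. Apobec3, a restriction factor against retroviruses, Serhl and Lgals2, a lectin of the gut epithelium, were lower. Enterocyte and lipid uptake genes were higher and MHC class II genes lower as sets, but not with an estimated correlation (adjusted p = 0.58 each). The first 2 also lost their call without library 13 (0.51 and 0.57) and turned within runs 1 and 3.

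Cyb5r3 (ENSMUSG00000018042, chromosome 15, 83153494 to 83172592) was at 283 ± 19.4 CPM (SD, n = 4) in PparA and 80.3 ± 14.9 CPM in WT, a log2 fold change of 1.81 ± 0.14 (adjusted p = 1e-09). Apobec3 (ENSMUSG00000009585, chromosome 15, 79891659 to 79915906) was at 38.5 ± 11.7 and 131 ± 1.7 CPM (−1.76 ± 0.26; 0.00018). Cmbl, Hsd17b13, Serhl and Lgals2 changed by 1.77 ± 0.28, 2.03 ± 0.36, −1.36 ± 0.26 and −0.52 ± 0.11 (adjusted p = 0.00054, 0.0026, 0.0059 and 0.015). Serhl was lost without library 17 (0.053) and Lgals2 without 17 (0.091) or 29 (0.094). Of 33 called genes 25 were higher and 10 were annotated as pseudogenes, with 522 genes at an unadjusted p under 0.05. The count was 19, 16, 18, 14 and 19 without libraries 1, 9, 13, 17 and 29, 14 within runs 1 and 3 and 65 within runs 2 and 4, of which 11 and 15 were among the 33. On chromosome 15, which carries Ppara, lay 10 of the 33, against 218 of the 5872 tested (Fisher's exact test, two-sided p = 1.77e-07).

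Summed enterocyte markers were at 1670 ± 906 CPM in PparA and 1100 ± 18.8 CPM in WT on the control diet, and the list was higher (median 0.89, 3 when adjusted over the list alone; adjusted p = 0.00044, and 0.58 with an estimated correlation). Lipid uptake genes were higher (median 0.68, 5 when adjusted over the list alone; 0.0041, and 0.58 with an estimated correlation). Apoa1, a lipoprotein component, was at 263 ± 316 and 36.8 ± 24.9 CPM and was called without library 21 (0.034). Sis, the sucrase of the brush border, was at 65.6 ± 91.5 and 12.7 ± 6.94 CPM (adjusted p = 0.34). Within runs 1 and 3 both were lower, with log2 fold changes of −0.87 and −1.62. Those of MHC class II were lower (median −1.04; 0.00047, and 0.58 with an estimated correlation), with H2-Ab1 at 36.5 ± 24.8 and 100 ± 33.2 CPM. Tuft cell markers were lower (−0.69; 0.043, and 0.58 with an estimated correlation), but not without 1, 9, 13 or 21 (0.066 to 0.35). Mitochondrially encoded transcripts were higher (0.15, 3 when adjusted over the list alone; 0.0019, and 0.35 with an estimated correlation). The fatty acid oxidation list did not pass (median 0.11; 0.25, and 0.92 with an estimated correlation), with 0.51 within runs 1 and 3 and 0.34 within runs 2 and 4 (0.25 to 0.98 over the alternatives). It passed without library 1 (0.041) or 29 (0.038).

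On the control diet PparDA stem cells had higher Acaa2, Acadl and Angptl4 than WT. The goblet genes Clca1, Zg16 and Klk1 were higher, with Clec2h, an enterocyte surface lectin, Fgf1, a growth factor, Rep15, a regulator of membrane recycling, Itch, a ubiquitin ligase, and Aldh1a3, which makes retinoic acid. Apobec3 and Ldb3, a protein of muscle Z-discs, were lower. MHC class II genes were lower as a set, but not with an estimated correlation (adjusted p = 0.36).

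Acaa2, Acadl and Angptl4 had log2 fold changes of 0.69 ± 0.16, 1.49 ± 0.40 and 2.71 ± 0.72 in PparDA against WT (adjusted p = 0.013, 0.046 and 0.044). Acaa2 was lost without 17 (0.068), Acadl without 1, 9, 15, 17, 23, 26 or 31 (0.068 to 0.13) and Angptl4 without 1, 17, 23, 26 or 31 (0.076 to 0.19). Fgf1 (ENSMUSG00000036585, chromosome 18, 38838673 to 38929472) was at 148 ± 22 CPM (SD, n = 4) in PparDA and 5.38 ± 2.16 CPM in WT (4.74 ± 0.81; 0.001). Rep15, Itch, Aldh1a3, Apobec3 and Ldb3 changed by 3.34 ± 0.71, 2.91 ± 0.61, 3.36 ± 0.58, −2.07 ± 0.27 and −5.46 ± 0.97 (0.0082, 0.0082, 0.0011, 2.4e-05 and 0.0017). In all 110 genes were called, 72 higher, with 813 at an unadjusted p under 0.05. The count was 71, 61, 68, 71 and 57 without libraries 1, 9, 17, 26 and 31, 37 within runs 1 and 3 and 57 within runs 2 and 4, of which 26 and 41 were among the 110. On chromosome 15 lay 13 of the 110 (Fisher's exact test, two-sided p = 0.000194).

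In PparDA 17 of 19 fatty acid oxidation genes were higher than in WT on the control diet (median 0.35, 2 called and 4 when adjusted over the list alone; adjusted p = 2.5e-05, and 0.36 with an estimated correlation). It was at 0.024 within runs 1 and 3 and 3.1e-05 within runs 2 and 4 (1.5e-05 to 0.36 over the alternatives). PPAR targets were higher (0.47, 3 called and 3 when adjusted over the list alone; 0.0023, and 0.36 with an estimated correlation), as were lipid uptake genes (0.58; 0.011, and 0.45 with an estimated correlation). Goblet markers were higher (0.75, 3 called and 3 when adjusted over the list alone; 2.7e-05, and 0.36 with an estimated correlation). Clca1, Zg16 and Klk1 changed by 2.49 ± 0.60, 2.57 ± 0.66 and 1.04 ± 0.20 (0.023, 0.035 and 0.0043). Clca1 was lost without 1, 15, 17, 26 or 31 (0.052 to 0.086) and Zg16 without 1, 9, 15, 17, 23, 26 or 31 (0.057 to 0.13).

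Enterocyte markers were higher in PparDA on the control diet (1550 ± 206 against 1100 ± 18.8 CPM summed; median 0.60, 1 when adjusted over the list alone; adjusted p = 0.00035, and 0.43 with an estimated correlation). Clec2h (3.59 ± 0.90; 0.031) was the 1 called and was lost without 1, 9, 23, 26 or 31 (0.081 to 0.11). Paneth markers were higher (1.19; 0.049, and 0.57 with an estimated correlation), not so without 1, 9, 17 or 31 (0.1 to 0.85). MHC class II genes were lower (−1.79, 6 of 6 when adjusted over the list alone; 2.4e-05, and 0.36 with an estimated correlation), with H2-Ab1 at 28.5 ± 14.5 and 100 ± 33.2 CPM. Proliferation genes were lower (−0.16; 0.049, and 0.46 with an estimated correlation), not so without 1, 7, 17, 23 or 26 (0.051 to 0.34). Mitochondrially encoded transcripts were higher (0.08, 1 when adjusted over the list alone; 0.049, and 0.39 with an estimated correlation), not so without 7, 17, 23 or 26 (0.082 to 0.12). Of these mt-Nd4 was called (0.34 ± 0.09; 0.032), but not without 1, 9, 15, 17, 23 or 31 (0.058 to 0.13).

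**Figure D4:**
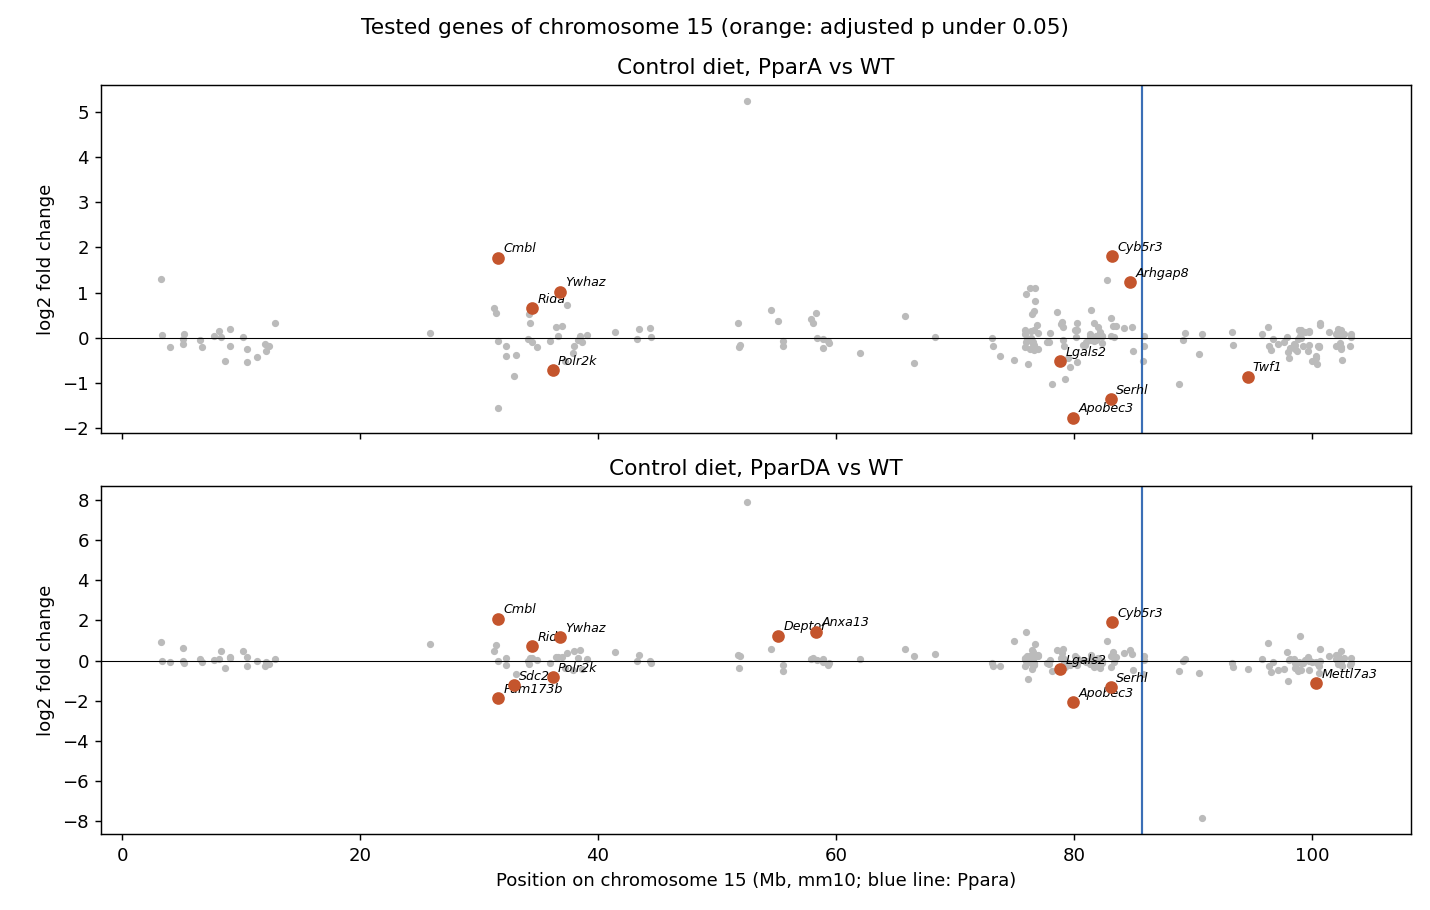
Log2 fold change of tested genes along chromosome 15 on the control diet, PparA against WT and PparDA against WT, by position in mm10, with Ppara marked by a blue line. Cyb5r3 was at 1.81 and Apobec3 at −1.76 in PparA.

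On the high-fat diet PparD stem cells had a lower Clta than WT. Fatty acid oxidation genes and PPAR targets were higher as sets, and Paneth, goblet and enteroendocrine markers were lower. These calls were lost with an estimated correlation (adjusted p = 0.41, 0.41, 0.42, 0.41 and 0.43).

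Clta was at 29.8 ± 4.91 CPM (SD, n = 4) in PparD and 145 ± 77.6 CPM in WT, a log2 fold change of −2.28 ± 0.40 (adjusted p = 0.017), and its call was lost without any 1 of 4, 10, 12, 18, 20 or 28 (0.064 to 0.14). In WT it stood at 158 to 205 CPM in libraries 2, 10 and 18 and at 32.6 CPM in library 25, and it differed between WT libraries by place. It was the 1 gene called (10 with the run as a factor), with 222 at an unadjusted p under 0.05. The count was 2 without library 2, 3 without library 25 and 0 without 4, 10, 12 or 20. Hacd3, an enzyme of fatty acid elongation (−1.48 ± 0.30), and Magohb (−1.05 ± 0.22) missed the threshold (0.069 each) and were gained without library 25 (0.027) and 28 (0.039). Runs 1 and 3 called 3 genes, 1 of them Clta, and runs 2 and 4 called 0. Angptl4 was at 27.7 ± 5.76 and 7.2 ± 3.09 CPM, and Slc25a20, the carnitine carrier, at 76.8 ± 3.13 and 39.6 ± 11.2 CPM, not called (adjusted p = 0.43 and 0.52).

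On the high-fat diet 16 of 19 fatty acid oxidation genes were higher in PparD than in WT (median 0.22, 1 when adjusted over the list alone; adjusted p = 1.2e-05, and 0.41 with an estimated correlation). It was at 0.00034 within runs 1 and 3 and 0.019 within runs 2 and 4 (7.9e-07 to 0.41 over the alternatives). PPAR targets were higher (0.20, 3 when adjusted over the list alone, 1 of them lower; 0.0044, and 0.41 with an estimated correlation), not so without library 2 (0.093). All 15 Paneth markers were lower (−1.51; 3.1e-06, and 0.42 with an estimated correlation). All 12 goblet markers were lower (−0.50; 8.9e-05, and 0.41 with an estimated correlation). Enteroendocrine markers were lower (−0.91; 0.0057, and 0.43 with an estimated correlation), not so without library 10 (0.17).

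On the high-fat diet PparA stem cells had higher Cyb5r3, Deptor and the cytokine Il18 than WT, and higher Rps4x, Rpl28 and Trmt112. Apobec3, Cyp2c65, which oxidises arachidonic acid, and Mptx2, a pentraxin of Paneth cells, were lower. Enterocyte and lipid uptake genes were higher as sets, but not with an estimated correlation (adjusted p = 0.6 each), and both turned within runs 1 and 3 (0.93 each). Fatty acid oxidation genes did not pass as a list.

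Cyb5r3 was at 285 ± 41.1 CPM (SD, n = 4) in PparA and 79.4 ± 3.62 CPM in WT, a log2 fold change of 1.84 ± 0.14 (adjusted p = 7.3e-10). Deptor, Il18, Rps4x, Rpl28 and Trmt112 changed by 1.95 ± 0.24, 1.94 ± 0.43, 1.51 ± 0.16, 1.5 ± 0.21 and 1.52 ± 0.18 (4.9e-06, 0.021, 6.9e-07, 3.1e-05 and 2.9e-06). Apobec3, Cyp2c65 and Mptx2 changed by −2.05 ± 0.27, −1.45 ± 0.28 and −5.42 ± 1.21 (1.6e-05, 0.0049 and 0.022). Il18 was lost without 2, 10, 14, 18, 25 or 30 (0.057 to 0.13) and Mptx2 without 2 (0.16), 14 (0.08) or 30 (0.087). Of 44 called genes 29 were higher and 8 were pseudogenes, with 687 at an unadjusted p under 0.05. The count was 23, 96, 26, 27, 75 and 27 without libraries 2, 6, 10, 18, 22 and 30, 18 within runs 1 and 3 and 105 within runs 2 and 4, of which 15 and 21 were among the 44. On chromosome 15 lay 8 of the 44 (Fisher's exact test, two-sided p = 0.000177).

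All 13 enterocyte markers were higher in PparA on the high-fat diet (median 1.13, 5 when adjusted over the list alone; adjusted p = 2.6e-05, and 0.6 with an estimated correlation). Lipid uptake genes were higher (0.85, 7 when adjusted over the list alone; 0.00017, and 0.6 with an estimated correlation), not so without library 14 (0.088). Apoa1 (3.10 ± 0.81; 0.064), the phosphatase Alpi (3.54 ± 0.99; 0.091) and the lactase Lct (4.27 ± 1.21; 0.096) were gained without library 6 (0.016, 0.02 and 0.035) or 22 (0.021, 0.023 and 0.026). Genes of the proximal small intestine were higher (0.71, 2 when adjusted over the list alone; 0.025, and 0.6 with an estimated correlation), not so without library 14 (0.19). Oxidative phosphorylation genes were lower (−0.13; 0.028, and 0.6 with an estimated correlation), not so without 10, 14, 22 or 30 (0.053 to 0.16). The fatty acid oxidation list had a median of 0.02 while camera put it lower (0.84, and 0.97 with an estimated correlation), at 0.93 within runs 1 and 3, turned, and 0.58 within runs 2 and 4 (0.58 to 0.97 over the alternatives).

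On the high-fat diet PparDA stem cells had a lower Acadvl than WT, the enzyme that starts β-oxidation of long-chain fatty acids. Fgf1, Rep15 and AA465934, an uncharacterised transcript, were higher, and Apobec3, Cyp2c65, Pnp2, a purine phosphorylase, Ldb3 and Mptx2 were lower. Enterocyte genes were higher and MHC class II genes lower as sets, but not with an estimated correlation (adjusted p = 0.76 each).

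Acadvl (ENSMUSG00000018574, chromosome 11, 70010183 to 70015411) was at 60.9 ± 5.8 CPM (SD, n = 4) in PparDA and 141 ± 30.9 CPM in WT, a log2 fold change of −1.21 ± 0.19 (adjusted p = 0.00036). Fgf1, Rep15 and AA465934 changed by 5.17 ± 0.85, 3.3 ± 0.70 and 4.73 ± 1.02 (0.00063, 0.0094 and 0.011). Apobec3, Cyp2c65, Pnp2, Ldb3 and Mptx2 changed by −2.01 ± 0.27, −1.49 ± 0.28, −4.75 ± 1.12, −3.10 ± 0.68 and −5.19 ± 1.18 (4.1e-05, 0.0037, 0.02, 0.012 and 0.014). Pnp2 was lost without 8 (0.071), 24 (0.052) or 32 (0.069), Ldb3 without 8 (0.05) and Mptx2 without 2 (0.14), 8 (0.06) or 16 (0.06). Of 92 called genes 55 were higher and 15 were pseudogenes, with 800 at an unadjusted p under 0.05. The count was 61, 59, 61 and 57 without libraries 8, 16, 18 and 25, 38 within runs 1 and 3 and 36 within runs 2 and 4, of which 22 and 30 were among the 92. On chromosome 15 lay 11 of the 92 (Fisher's exact test, two-sided p = 0.000546).

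The fatty acid oxidation list did not pass in this comparison (median −0.08, 3 called lower and 4 when adjusted over the list alone, 1 of them higher; adjusted p = 0.14, and 0.76 with an estimated correlation), at 0.98 within runs 1 and 3 and 0.0052 within runs 2 and 4 (0.0052 to 0.98 over the alternatives), and passed without library 2 (0.029). The fry test of change in either direction gave an adjusted p of 0.0083. All 13 enterocyte markers were higher in PparDA (median 1.01, 4 when adjusted over the list alone; 1.6e-05, and 0.76 with an estimated correlation), with Sis at 71.2 ± 28 and 10.8 ± 8.25 CPM. Lipid uptake genes were higher (0.59; 0.019, and 0.76 with an estimated correlation), with Apoa1 at 191 ± 85.6 and 37.1 ± 8.3 CPM, not so without 8, 18 or 32 (0.07 to 0.09). Those of MHC class II were lower (−1.31; 0.0044, and 0.76 with an estimated correlation), not so without library 18 (0.13) or 24 (0.081). Mitochondrially encoded transcripts were higher (0.25, 4 when adjusted over the list alone; 0.0017, and 0.27 with an estimated correlation).

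Against PparD on the same high-fat diet, PparDA stem cells had lower Acadvl, Eci2 and Slc25a20, and the fatty acid oxidation list was lower as a set. Fgf1 and Rep15 were higher and Apobec3 lower, and enterocyte, antimicrobial and goblet genes were higher as sets. With an estimated correlation the 4 list calls were lost (adjusted p = 0.14, 0.43, 0.19 and 0.56).

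Acadvl was at 60.9 ± 5.8 CPM (SD, n = 4) in PparDA and 154 ± 28.7 CPM in PparD, a log2 fold change of −1.33 ± 0.19 (adjusted p = 0.00011). Eci2, Slc25a20, Fgf1, Rep15 and Apobec3 changed by −1.23 ± 0.22, −1.12 ± 0.27, 4.66 ± 0.80, 3.49 ± 0.71 and −1.72 ± 0.27 (0.0026, 0.026, 0.0015, 0.0075 and 4e-04). Slc25a20 was lost without 4, 8, 12, 20, 24, 28 or 32 (0.055 to 0.084). Of 93 called genes 53 were higher, with 721 at an unadjusted p under 0.05. The count was 32, 54, 47, 56, 42, 56 and 34 without libraries 4, 8, 12, 16, 20, 24 and 28, 33 within runs 1 and 3 and 36 within runs 2 and 4, of which 22 and 30 were among the 93. On chromosome 15 lay 13 of the 93 (Fisher's exact test, two-sided p = 3.32e-05).

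In this comparison 16 of 19 fatty acid oxidation genes were lower (median −0.25, 3 called and 5 when adjusted over the list alone; adjusted p = 3e-07, and 0.14 with an estimated correlation). The list was at 0.005 within runs 1 and 3 and 3.2e-07 within runs 2 and 4 (6.7e-08 to 0.14 over the alternatives). PPAR targets were lower (−0.23, 1 called and 4 when adjusted over the list alone; 0.0091, and 0.43 with an estimated correlation), not so without library 16 (0.11). Enterocyte markers were higher (1.09, 1 when adjusted over the list alone; 1.3e-05, and 0.43 with an estimated correlation), with Sis at 71.2 ± 28 and 5.75 ± 4.84 CPM. Antimicrobial genes were higher (1.93, 3 when adjusted over the list alone; 0.0091, and 0.19 with an estimated correlation), not so without library 16 (0.11). Goblet markers were higher (0.42, 2 when adjusted over the list alone; 0.0091, and 0.56 with an estimated correlation), not so without library 4 (0.073) or 24 (0.17). Mitochondrially encoded transcripts were higher (0.23, 2 when adjusted over the list alone; 0.0013, and 0.14 with an estimated correlation). Glycolysis genes were higher (0.23; 0.046, and 0.56 with an estimated correlation), not so without 4, 16, 28 or 32 (0.06 to 0.11).

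Against PparA on the high-fat diet, PparDA stem cells had lower Rps4x, Rpl28, Rps26 and Trmt112, of which Rps4x, Rpl28 and Trmt112 were higher on the high-fat diet in PparA. Acy1, an aminoacylase, and Rab25 were higher. MHC class II genes were lower and glycolysis genes higher as sets, but not with an estimated correlation (adjusted p = 0.88 each), and the former turned within runs 2 and 4.

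Rps4x was at 8740 ± 782 CPM (SD, n = 4) in PparDA and 26600 ± 3770 CPM in PparA, a log2 fold change of −1.61 ± 0.16 (adjusted p = 3.4e-07). Rpl28, Trmt112, Rps26, Acy1 and Rab25 changed by −1.52 ± 0.21, −1.5 ± 0.18, −0.74 ± 0.12, 0.93 ± 0.18 and 0.79 ± 0.14 (8e-05, 6.3e-06, 0.00079, 0.0072 and 0.0034). Of 16 called genes 6 were higher, with 734 at an unadjusted p under 0.05. The count was 26, 28, 27 and 34 without libraries 6, 14, 24 and 32, 60 within runs 1 and 3 and 11 within runs 2 and 4, of which 7 and 2 were among the 16. DESeq2 called 128, of which 13 were among the 16, and edgeR with the run as a factor called 146. On chromosome 15 lay 1 of the 16 (Fisher's exact test, two-sided p = 0.455).

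MHC class II genes were lower in PparDA than in PparA (median −1.06, 1 when adjusted over the list alone; adjusted p = 0.018, and 0.88 with an estimated correlation), not so without library 24 (0.2). Within runs 2 and 4 this list turned (0.87). Glycolysis genes were higher (0.30, 3 when adjusted over the list alone; 0.023, and 0.88 with an estimated correlation), not so without library 22 (0.23) or 32 (0.066). The fatty acid oxidation list did not pass (−0.09, 1 when adjusted over the list alone; 0.23, and 0.9 with an estimated correlation), with 0.7 within runs 1 and 3 and 0.05 within runs 2 and 4 (0.05 to 0.9 over the alternatives), but did without library 6 (0.015).

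A group of 9 lists passed in none of the 15 comparisons. Their smallest camera adjusted p were 0.094 for peroxisomal fatty acid oxidation, 0.15 for ketone body metabolism, 0.23 for LXR targets, 0.48 for Wnt target and Notch ligand genes and 0.073 for the interferon response. For the distal small intestine, the tricarboxylic acid cycle, NRF2 targets and the unfolded protein response they were 0.092, 0.15, 0.081 and 0.086. The tricarboxylic acid cycle had at most 1 called member in a comparison, and 7 of these lists had 0. Markers of lymphocytes (4.33 to 44.8 CPM summed per library), stromal and endothelial cells (3.03 to 21.5 CPM), red blood cells (0 to 9.92 CPM) and the early response to dissociation (94.7 to 187 CPM) had too few tested members for a test.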

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

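The tests by place in the run, of splits within runs, of swapped labels, of the chromosome 15 window and of leaving out 1 library were chosen after the result was seen.

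Within groups of 4 libraries, 1 library stood far from the other 3 in 25 of 272 cases, where chance gives about 1 in 20 groups, or 13.6. In WT control these were Acadvl in library 1 (95 CPM; others 66.5 to 68.7), Apoa1 and Clec2h in library 17 (74 and 4.53 CPM; others 22.7 to 27.2 and 0), and in library 26 Ang4 (239; 16 to 37.5), Clta (153; 37.5 to 46.8), Eci2 (85.9; 68.2 to 69.8), Fgf1 (8.59; 4.01 to 4.53), Rab25 (74.5; 81.5 to 81.6) and Rps4x (9420; 6270 to 6700). In WT high-fat they were Tnfrsf19 in library 2 (7.18; 14.2 to 14.8), Golga1 in library 10 (7.41; 15.6 to 17), Cd74, H2-Ab1 and H2-Eb1 in library 18 (397, 125 and 99.2; 94.8 to 122, 28.7 to 43 and 19.9 to 24.4), and Acadvl (187; 124 to 127) and Rps4x (5180; 10400 to 11400) in library 25.

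In PparD they were Sst in control library 19 (2.96 CPM; others 0) and Tff3 in high-fat library 28 (1190; 751 to 808). In PparA the case was Rps26 in high-fat library 22 (2780; 2410 to 2450). In PparDA they were Fgf1 and Lyz1 in control library 31 (181 and 4090; 134 to 140 and 255 to 719), Reg3b in high-fat library 16 (4100; 73 to 600), and Cops2, Eci2 and Rep15 in high-fat library 24 (126, 97.8 and 1200; 109 to 111, 78.4 to 79.8 and 876 to 909).

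Of the diet effects that differed from that in WT by a test of the difference itself, 18 are named here. In PparD these were Rps24 (−2.55) and Clta (−2.75), and by list median fatty acid oxidation (−0.20), PPAR targets (−0.39), cholesterol synthesis (−0.35) and antimicrobial genes (−2.50). In PparA they were Deptor (1.57), Rab25 (−1.03), Rpl28 (2.28), Trmt112 (1.49), Hint1 (0.79), Rps4x (1.51), Golga1 (1.77) and Anp32a (−1.25). In PparDA they were the medians of fatty acid oxidation (−0.48), PPAR targets (−0.52), Paneth markers (−1.71) and goblet markers (−0.61). None of the list results here passed with an estimated correlation.

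Clta, Rps4x, Rps24 and other genes followed the library number. Splitting the 8 WT libraries by place in the run called 9 genes, against 6 by diet, and 2 of the 12 genes called by diet in PparD or PparA were among these. A candidate source in WT is therefore the place in the run, such as a position in library preparation. Swapped labels of libraries 25 and 26 are argued against, since the fatty acid oxidation list had a median log2 ratio of 0.53 in library 25 over 26, with 15 of 19 genes above 0, against 0.14, 0.74 and 0.44 for high-fat over control in runs 1 to 3. In PparD and PparA, place and diet cannot be told apart, because 0 groups had libraries at more than 1 place, and a diet effect on these genes stays open.

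Genes called in any of the 4 comparisons of PparA or PparDA with WT gathered on chromosome 15, with 18 of 180 called against 218 of 5872 tested (Fisher's exact test, two-sided p = 0.00011, adjusted p = 0.0022 over 20 chromosomes). Reads shared with pseudogenes are argued against by protein-coding genes alone, with 17 of 152 (Fisher's exact p = 3.4e-05). Strain variants within 20 Mb of Ppara as the whole cause are argued against by the rest of the chromosome, with 10 called (Fisher's exact p = 6.3e-05). The window held 8 of 144 tested (p = 0.085), not denser than the rest of the chromosome (odds ratio 0.378, Fisher's exact p = 0.066). A longer segment of another strain carried with the Ppara allele stays open and was not tested. Loss of Ppara as a regulator cannot be told apart from it, since 0 canonical PPAR targets were among these genes and other targets are possible.

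Fatty acid oxidation genes were higher in PparD than in WT on the control diet. A single library is argued against by the highest adjusted p on leaving 1 out, 8e-08, and more absorptive cells by the median of enterocyte markers, −0.26. Place in the run cannot be told apart, since PparD libraries stood at other places than WT. In WT the list had a camera p of 5e-04 by place, but 11 of 35 splits of the 8 libraries gave one as small (exact permutation p = 0.31), and the split by place differs from that by diet in only 2 libraries. An effect of the Ppard alleles stays open as a hypothesis.

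For gene counts, the libraries of each comparison were also split in every other way, or in 100 draws for differences of diet effects. These were fits of only the libraries compared, without regard to the run, and most of their real counts differ from those of the full model. Chance is argued against for PparA and PparDA against WT on the control diet. There 1 of 35 splits gave as many, the real one: 13 and 102 genes against at most 5 and 5. For PparD against WT on that diet the same holds of these splits (11 against 6), but not of those within runs below, which leaves chance open. Chance is also argued against for PparA and PparDA against WT on the high-fat diet (18 and 108 against 4 and 5, 1 of 35 each). The same holds for PparDA against PparD (144 against 4, 1 of 35). In these 6 comparisons the highest other split set runs 1 and 3 against runs 2 and 4. For the difference in PparA 2 of 100 splits gave at least the 4 genes of this fit, with 59 in another. Libraries moved between genotypes in those splits, so they cannot decide on chance there. For the difference in PparDA 4 of 100 splits gave at least the 2 genes of this fit, with 111 in another, but the full model called 0 genes, so that no reported call rests on this. By these splits chance cannot be excluded for the diet in WT (3 against 25; 4 of 35), PparD (11 against 14; 2 of 35) and PparA (4 against 216; 3 of 35). For the diet in PparDA this fit called 0 genes, so that 35 of 35 splits gave as many (8 at most), and the test decides nothing on the 2 genes reported. Nor can chance be excluded for the difference in PparD (3 against 17; 7 of 100), PparD against WT on the high-fat diet (1 against 10; 5 of 35) or PparDA against PparA (6 against 6; 2 of 35). The highest split followed runs 1 and 3, which also differ in Xist, for PparD, PparA, PparD against WT and PparDA against PparA, and runs 1 and 2 for PparDA. With the run as a factor these 5 comparisons had 14, 18, 10, 146 and 9 genes. Swapping groups only within runs, with the run as a factor, leaves 8 splits, too few for a share under 0.05. The real split then called the most genes for the diet in WT, PparD, PparA and PparDA (23, 39, 45 and 8 against at most 12, 27, 5 and 7 in the others) and PparDA against PparA (43 against 12), but not for PparD against WT on the high-fat (7 against 10) or control diet (19 against 26). The 216 genes in PparA point to a structure of the libraries other than their group.

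For the fatty acid oxidation list the real split had the smallest camera p, so that chance can be excluded, for the diet in WT (7.3e-16 against 3.1e-13), PparD (2.4e-08 against 9.7e-05), PparD against WT on the high-fat (8.8e-08 against 1.5e-05) and control diet (9.1e-13 against 3e-08) and PparDA against PparD (1.7e-08 against 4e-06), each 1 of 35. For the difference in PparDA the real split also had the smallest p (3.2e-12 against 6.2e-08, 1 of 100). Libraries moved between genotypes in those splits, so they cannot decide on chance there. Chance cannot be excluded for the diet in PparA (9.2e-07 against 8.8e-16; 3 of 35) and PparDA (0.78 against 0.034; 27 of 35), or the differences in PparD (0.0024 against 1.4e-14; 25 of 100) and PparA (0.14 against 2.7e-07; 53 of 100). Nor can it for PparA and PparDA against WT on the high-fat diet (0.88 against 5.6e-06, 33 of 35; 0.037 against 0.00082, 6 of 35) and on the control diet (0.14 against 7.6e-06, 21 of 35; 3.8e-05 against 6.5e-07, 4 of 35), or PparDA against PparA (0.073 against 2.1e-06; 19 of 35).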

How the results depend on the processing

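The fits with the run as a factor, with runs 1 and 3 or runs 2 and 4 alone, without library 5 and with other variance models were chosen after seeing the data. Values below follow one order: the diet in WT, PparD, PparA and PparDA, its difference from WT in PparD, PparA and PparDA, PparD, PparA and PparDA against WT on the high-fat and then on the control diet, and PparDA against PparD and against PparA. Unless stated, the cause was not tested.

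The reported counts were 6, 5, 8, 2, 3, 9, 0, 1, 44, 92, 12, 33, 110, 93 and 16. Median-of-ratios factors gave 6, 5, 7, 2, 3, 10, 0, 1, 44, 90, 11, 34, 110, 90 and 17, and moved the median log2 fold change of a comparison by at most 0.008. At least 20 CPM gave 6, 7, 8, 2, 3, 11, 0, 5, 45, 88, 10, 35, 109, 90 and 40. DESeq2 gave 7, 13, 11, 35, 8, 7, 1, 6, 73, 102, 12, 43, 113, 89 and 128. Fits of only the libraries compared gave 3, 11, 4, 0, 3, 4, 2, 1, 18, 108, 11, 13, 102, 144 and 6. The run as a factor gave 7, 14, 18, 9, 5, 22, 4, 10, 93, 128, 22, 53, 165, 136 and 146, and held all reported genes but 1. Runs 1 and 3 gave 5, 2, 4, 0, 6, 3, 2, 3, 18, 38, 13, 14, 37, 33 and 60, and runs 2 and 4 gave 4, 2, 8, 0, 1, 1, 1, 0, 105, 36, 3, 65, 57, 36 and 11, with fewer libraries. Without library 5 the counts were 6, 6, 11, 2, 5, 12, 1, 1, 52, 94, 11, 37, 120, 99 and 16. Leaving out each library gave 0 to 7, 4 to 5, 5 to 14, 1 to 3, 2 to 6, 4 to 16, 0 to 2, 0 to 3, 23 to 96, 57 to 76, 7 to 15, 14 to 46, 57 to 97, 32 to 64 and 11 to 34.

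Without a filter the counts were 99, 78, 106, 59, 55, 80, 71, 83, 288, 301, 85, 210, 327, 286 and 212. Over 21299 genes the prior degrees of freedom became infinite, so that the quasi-dispersion of Fabp1 went from 6.514 to 0.3894, which accounts for such calls. A robust prior gave 4, 11, 13, 2, 3, 10, 0, 6, 40, 93, 13, 27, 112, 86 and 39, bias-adjusted deviances 6, 5, 8, 2, 5, 10, 0, 1, 55, 98, 12, 42, 124, 106 and 29, and both 4, 11, 13, 2, 3, 10, 0, 6, 46, 103, 14, 32, 119, 103 and 40. Without a filter, the robust prior gave 13, 11, 19, 18, 5, 17, 1, 13, 87, 132, 23, 49, 138, 132 and 100, bias-adjusted deviances 89, 70, 96, 54, 45, 71, 60, 77, 288, 295, 80, 207, 333, 286 and 197, and both 11, 13, 19, 10, 5, 14, 2, 14, 91, 146, 24, 57, 143, 143 and 95.

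The fatty acid oxidation list kept its direction and side of the threshold in all 15 comparisons with median-of-ratios factors, at least 20 CPM, only the libraries compared and the run as a factor. With an estimated correlation its adjusted p were 0.012, 0.14, 0.17, 1, 0.9, 0.89, 0.087, 0.41, 0.97, 0.76, 0.042, 0.92, 0.36, 0.14 and 0.9. Within runs 1 and 3 they were 0.0041, 0.0017, 0.015, 0.93, 0.72, 0.84, 0.059, 0.00034, 0.93, 0.98, 0.00049, 0.51, 0.024, 0.005 and 0.7, with the direction turned for the diet in PparDA and for PparA on the high-fat diet. Within runs 2 and 4 they were 2.2e-17, 3.9e-05, 1.2e-06, 0.61, 0.00073, 0.3, 3.1e-11, 0.019, 0.58, 0.0052, 4.6e-10, 0.34, 3.1e-05, 3.2e-07 and 0.05. Without library 5 it turned for PparA on the control diet (0.98). Leaving out each library gave 5.6e-17 to 9.9e-10, 5.1e-07 to 0.00022, 2.1e-12 to 0.00074, 0.6 to 0.99, 0.0032 to 0.2, 0.054 to 0.95, 2.1e-11 to 2e-07, 5.8e-06 to 0.0041, 0.23 to 0.98, 0.029 to 0.32, 3.2e-13 to 8e-08, 0.038 to 0.98, 1.8e-06 to 0.00074, 1.4e-07 to 3.3e-05 and 0.015 to 0.93.

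The other lists had 70 calls, of which 1 passed with an estimated correlation. The diet calls shared by genotypes were 1, with 98 without a filter and 4 with the run as a factor. Lists that turned were lipid uptake and enterocyte markers for PparA on the high-fat diet (0.93 and 0.93) and on the control diet (0.37 and 0.098) within runs 1 and 3, and MHC class II for PparDA against PparA within runs 2 and 4 (0.87).

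Log2 fold changes that turned were those of Lgr5 in WT within runs 1 and 3 (0.33) and without library 26 (0.18; −0.23 to 0.18 leaving out each), and Plin2 in WT within runs 2 and 4 (0.02). For PparA on the control diet Apoa1 (−0.87) and Sis (−1.62) turned within runs 1 and 3, as did Alpi (−1.06) on the high-fat diet.

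No paired analysis was possible because the columns carry no replicate number, going by labels alone. In order, the sample titles match the library numbers, with the run of 8 as the replicate. The run was fitted as a block (counts above). Depth limits genes near the floor of 3 counts, 4.14 to 4.9 CPM: Ppara, Ppard and Pdk4 could not be tested. Among simulated genes of at least 10 CPM, 1.5-fold changes were called in 16.4%.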

Other observations

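The comparison by runs within PparA was chosen after the result was seen, and the values by library below were not planned.

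The PparA libraries of runs 1 and 3 differed from those of runs 2 and 4 in many genes, some of which set PparDA apart from WT. PparA means mix both kinds. On the first principal component (17.5%) runs 2 and 4 of PparA stood at 16.8 to 28.3, near PparDA (9.7 to 23.4). Runs 1 and 3 stood at −8.4 to −5.5, near WT and PparD (−16.9 to −8.2). No list was tested here.

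Between runs 1 and 3 and runs 2 and 4, 216 genes were called among the 8 PparA libraries, 66 of them higher in runs 1 and 3, against 9 in WT, 14 in PparD and 6 in PparDA. The log2 differences, runs 1 and 3 over runs 2 and 4, were −3.92 for Apoa1, −4.52 for Sis, −5.28 for Alpi, −2.91 for Defa29, −3.12 for Defa31, −4.28 for Fgf1, −3.70 for Rep15, −3.20 for Itch, −5.25 for AA465934, 6.15 for Pnp2 and 3.83 for Ldb3. The sex-linked Xist and Eif2s3y differed by 8.01 and −8.53.

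After group means were removed, the median correlation across genes was 0.15 (−0.035 to 0.44) for the 112 pairs of libraries of the same run, 84 of them above 0.1, and −0.06 for pairs of different runs. Genes are not independent replicates, so these correlations carry no test. Between replicates, the chi-square per degree of freedom ran from 1.99 to 7.93 over 48 pairs, where counting error alone gives 1.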
